A study of Homo sapiens with 22 samples.

How the data were processed

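The series holds 22 samples. RNA-seq covered 8 libraries in 4 groups of 2 (WT and KO, hESC and hMSC). ChIP-seq of hMSC covered H3K4me3 and H3K27me3 with 1 library per genotype and H3K9me3 with 2 per genotype, and RRBS covered 1 library per genotype. The IgG sample and the 3 input samples were not analysed here. Groups and replicate numbers were taken from the sample titles. Per the labels, replicate 1 of both genotypes of H3K9me3 used one antibody lot and replicate 2 another.

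The RNA-seq values are whole read counts per gene, which per the file headers are reads per gene with a total for each library. The counts in genes summed to 99.1 to 99.7% of that total. The deposited RPKM values equal the counts divided by the gene length in the file and by the header total, to within 5.5e-12, and were not used for tests. The submitters' processing notes name CASAVA 1.8, BWA, MACS 1.4 and the hg19 build. The program that counted reads, the gene annotation and any use of strand are not given in the sources used here, so genes that overlap or share near-identical copies are uncertain. The peak files are deposited lists of intervals with a score per peak, 1 list per library and not pooled, and the score is the authors' own value from the peak caller. The scores start at 50.0 in the H3K4me3 and H3K9me3 lists, except at 50.6 in H3K9me3 of KO replicate 1, and at 128 and 129 in the H3K27me3 lists. The control library used for each call is not given in the sources used here. The deposited RRBS files list, per the file headers, the count of methylated reads and the count of all reads for each CpG cytosine, with the strands apart. The bisulfite aligner is not given in the sources used here.

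All choices of design, alternatives, gene lists and naming rules were made before the data were examined, except where said otherwise. Of 23407 genes in the files, 14281 passed edgeR's filterByExpr over the 4 groups. Counts were scaled by TMM and tested with edgeR 4.0.16 (quasi-likelihood, robust) in one model of the 4 groups without a replicate term. P-values were adjusted by Benjamini-Hochberg with a threshold of 0.05 and no minimum fold. The KO effect was tested in hMSC and in hESC, as the difference of these effects, and WT hMSC were compared with WT hESC. CPM values are counts per 1000000 reads after TMM scaling, given as mean ± SD of 2 libraries. The common biological coefficient of variation was 24.8% over all 8 libraries, 7.3% in the hMSC libraries alone and 32.6% in the hESC libraries alone, so the shared estimate is wide for hMSC. For a gene without reads in a group, a fold was computed against 3 reads in each library. If both mates of a fragment were counted, 3 reads stand for fewer fragments, and these folds are less certain as lower limits. On simulated counts with 200 changed genes the test recovered 19% of genes changed by a log2 of 1 and 75% of those changed by 2 in hMSC, with 11 false calls among 14075 genes. In hESC it recovered 13 and 81%, with 13 false calls among 14065 genes. With 100 genes changed by each size, the false calls were a larger share of all calls than 0.05 in both cell types. The simulated counts used a spread shared by the 4 groups and no shift common to same-numbered libraries. The real hESC libraries varied more and deviated together by number, so these shares do not give the power of the hESC comparison.

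Of the 35 gene lists fixed beforehand, the 32 with 5 or more tested genes were tested with camera in limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01), adjusted over the lists, and again with an estimated correlation. The genes named are WRN, fixed key genes, up to 2 genes with the largest rise and 2 with the largest fall of each list with a member past the threshold, and the 6 largest rises and falls among genes with a mean of at least 5 CPM in a group and KO libraries all outside the WT range. For the difference between cell types the 3 largest each way were named. A few genes that meet these rules are not reported here and are left out of the counts of named results. Values of single list members other than the key genes that the text gives for hESC lie outside that rule and were chosen after their values were seen, as were the 2 genes POU5F1 and FN1 in hMSC.

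Peaks on chromosomes 1 to 22 and X were used. Covered length is the union of the peaks of a library. A peak counted as shared with an overlap of 1 bp or more, and 95% Wilson intervals of the shares cover counting error only. For H3K9me3 the percent of each 1 Mb window covered was taken as log2(percent + 1) and tested with limma (trend, robust) with the antibody lot as a block, in the 2780 windows with at least 1% covered in 2 or more libraries. On simulated windows the test recovered 0% of 200 windows changed by a log2 of 1 or of 2. Read depths of the ChIP-seq libraries are unknown here. The RRBS files held 21478323 reads at sites in WT and 17630129 in KO. CpG sites with at least 10 reads in both libraries were compared by Fisher's exact test (scipy 1.17.1), adjusted by Benjamini-Hochberg, and called at adjusted p 0.05 with a difference of at least 20 percentage points. No molecular identifiers are named in the labels, so intervals and limits cover counting error only.

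No hg19 gene annotation was used, so peaks, windows and sites are given by hg19 position and are not tied to genes. Gene order along chromosomes was taken from RefSeq on a GRCh38 assembly, which placed 14239 of the 14281 tested genes (99.7%), and was used only to find neighbours. The alternatives were, for RNA, the replicate number as a block, the groups compared alone, DESeq2 1.42.0, its size factors within edgeR, no filter on low counts, a filter of 5 CPM, and each library left out. For peaks they were a stricter score, a larger overlap, equal numbers of peaks, merged peaks, other windows, another pseudocount and another centring. For RRBS they were other coverage minimums, no minimum difference and summed strands. Scripts ran in R 4.3.3 and Python 3.11.15.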

Results

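Werner syndrome is an inherited disease with signs of early ageing, caused by loss of WRN, a DNA helicase of the RecQ family. The samples compared wild-type (WT) cells with cells in which the WRN exons encoding the helicase domain had been deleted (KO). Both genotypes were studied as H9 human embryonic stem cells (hESC), an established pluripotent line, and as mesenchymal stem cells (hMSC), fibroblast-like progenitors of bone, cartilage and fat. The labels do not say how the hMSC were obtained: the deletion was made in hESC, while the culture notes mention MSCs from bone marrow, so a difference in origin between WT and KO hMSC is not excluded by the labels. Gene expression was measured by RNA-seq in 2 libraries of each genotype and cell type, 8 in all. In hMSC, peaks of H3K4me3 (a mark of active promoters) and H3K27me3 (the Polycomb mark) came from 1 library per genotype. Peaks of H3K9me3, the mark of constitutive heterochromatin, came from 2 libraries per genotype, and DNA methylation by reduced representation bisulfite sequencing (RRBS) came from 1 library per genotype. The RNA-seq files held 12987948 to 20632124 reads in genes per hESC library and 8181243 to 8999157 per hMSC library. No label says that the paired libraries came from separate cultures, so the p-values measure the spread between these libraries, which may be technical. The sample titles do not name clones either. What is called a KO effect here can therefore include other differences between the WT and KO cells. With each read taken as independent, the libraries of a pair differed by more than sampling noise in every group. The mean chi-square per gene was 105 and 90.8 in WT and KO hESC but 2.42 and 4.34 in WT and KO hMSC. Most low counts of the named genes were even numbers, as when both mates of a fragment are counted. Sampling noise would then be larger, and the WT hMSC value may be close to it.

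WRN itself was lower in every KO library than in every WT library of the same cell type. In hMSC it had 27.8 ± 3.63 counts per 1000000 reads (CPM) in WT and 7.51 ± 0.77 CPM in KO (SD, n = 2; log2 fold change -1.89, SE 0.48), with 25.2 and 30.3 CPM in the WT libraries and 6.96 and 8.05 CPM in the KO libraries. In hESC it had 70.4 ± 21.5 CPM in WT and 23.9 ± 15.8 CPM in KO (log2 fold change -1.56, SE 0.44), with 85.7 and 55.2 CPM in WT and 35.1 and 12.8 CPM in KO. The decrease did not pass the adjusted threshold in hMSC (adjusted p = 0.068) or hESC (adjusted p = 1). When the hMSC libraries were fitted alone, adjusted p was 3.9e-08. With the replicate number as a block adjusted p for WRN in hESC was 3e-07, and over all alternatives run it was 1e-29 to 1. The counts cover the whole gene, including exons outside the deletion, so reads in KO cells do not show that intact WRN was made.

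The labels of the cell types were checked in the WT libraries. All 21 tested pluripotency genes were lower in hMSC than in hESC, among them LIN28A, an RNA-binding protein of pluripotent cells, at 0.25 ± 0.35 against 1618 ± 439 CPM. PRDM14 had no reads in WT hMSC, against 56.9 ± 5.49 CPM in WT hESC. Of 22 mesenchymal genes 20 were higher in hMSC, including the surface marker NT5E (CD73; 708 ± 1.20 against 2.41 ± 0.23 CPM), COL3A1 (1878 ± 4.95 against 8.59 ± 2.42 CPM) and the transcription factor TWIST1 (25.6 ± 0.54 against 0.05 ± 0.08 CPM). In total 7742 of 14281 genes differed, 3487 higher and 4255 lower in hMSC.

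Genes of cell division fell together in KO hMSC. All 28 members of the G2/M list fell, with a median log2 fold change of -1.93. The mitotic kinesin KIF20A went from 125 ± 0.42 to 23.3 ± 0.26 CPM (log2 fold change -2.42, adjusted p = 0.002), and AURKB, a mitotic kinase, from 52.4 ± 3.01 to 11.2 ± 1.15 CPM. The proliferation marker MKI67 fell from 247 ± 6.65 to 68.5 ± 12.2 CPM (adjusted p = 0.0083). Of 30 DNA replication genes 22 fell, or 27 when adjusted over the list alone, and none rose. MCM5, a subunit of the replicative helicase, went from 92.2 ± 1.94 to 24.6 ± 4.24 CPM, and RRM2, a subunit of ribonucleotide reductase, from 224 ± 0.71 to 63.3 ± 10.8 CPM. Of 27 genes of double-strand break repair 7 fell and none rose (9 fell when adjusted over the list alone), with BRCA1 at 31.7 ± 1.68 CPM in WT and 9.60 ± 1.38 CPM in KO. BLM, another RecQ helicase, fell from 12 ± 2.27 to 4.25 ± 0.50 CPM and was the 1 member of the 5-gene RecQ list to pass. The 3 lists of division, replication and repair passed camera with a preset correlation of 0.01 (adjusted p = 7e-29, 4e-19 and 4.9e-06). With an estimated correlation none of the calls held (adjusted p = 0.13, 0.12 and 0.12).

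Single genes of the nuclear envelope, of heterochromatin and of Polycomb fell in KO hMSC, among them LMNB1, UHRF1 and EZH2. Among 16 genes of the nuclear envelope and lamina 5 fell and 1 rose. The lamin LMNB1 fell from 84.1 ± 1.85 to 24.5 ± 2.13 CPM (log2 fold change -1.78, adjusted p = 0.0068), TMPO, which encodes lamina-associated polypeptide 2, from 144 ± 1.13 to 45.5 ± 3.15 CPM, and LBR, the lamin B receptor, from 78.6 ± 0.66 to 31.6 ± 3.33 CPM, while SYNE1, a nesprin, rose from 59.4 ± 1.41 to 129 ± 14.8 CPM. This list did not pass camera (adjusted p = 0.078). In the list of H3K9 heterochromatin factors 3 of 20 fell and none rose over all genes tested, and 9 fell and 1 rose when adjusted over the list alone. With the hMSC libraries fitted alone 15 fell and 1 rose, where 2050 of all 12096 tested genes fell and 2038 rose. The median log2 fold change of this list was -0.47 and it passed camera (adjusted p = 0.00029), though not with an estimated correlation (adjusted p = 0.12). The members that fell over all genes tested were CHAF1A and CHAF1B, subunits of the chromatin assembly factor that acts at replication forks, and UHRF1, which recruits DNMT1 to replicating DNA. CHAF1B went from 25 ± 1.85 to 8.82 ± 1.90 CPM and UHRF1 from 162 ± 15.5 to 59.9 ± 6.22 CPM. The H3K9 methyltransferase gene SUV39H1 had 20.2 ± 1.65 CPM in WT and 11.3 ± 3.74 CPM in KO (adjusted p = 0.12), and CBX5, which encodes the H3K9me3-binding protein HP1 alpha, had 214 ± 18.5 and 148 ± 13.9 CPM (adjusted p = 0.3). When the hMSC libraries were fitted alone, adjusted p was 0.0033 for SUV39H1 and 2.8e-05 for CBX5. Of 18 Polycomb genes 2 fell, EZH2 (the H3K27 methyltransferase; 47.9 ± 2.86 to 13.4 ± 0.11 CPM) and PHF19 (83.7 ± 0.81 to 31.2 ± 5.88 CPM). Of 13 genes of DNA methylation 2 fell, UHRF1 and the maintenance methyltransferase DNMT1 (187 ± 5.59 to 103 ± 5.96 CPM). Neither of these lists passed camera (adjusted p = 0.099 and 0.14). Of 10 H3K9 demethylase genes none passed over all genes tested, and 3 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.77).

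Among the 7 tested inhibitors of cyclin-dependent kinases 2 rose and 2 fell. CDKN2B (p15) rose from 11.6 ± 1.93 to 61.0 ± 6.51 CPM (log2 fold change 2.39, adjusted p = 0.002), and CDKN2A, the p16 and ARF locus that marks senescence, rose from 19.5 ± 0.25 to 48.2 ± 1.29 CPM (adjusted p = 0.049). CDKN2C (p18) fell from 42.0 ± 2.67 to 7.72 ± 0.68 CPM and CDKN1B (p27) from 24.1 ± 0.13 to 12.6 ± 1.61 CPM. CDKN1A (p21) had 1001 ± 37.8 CPM in WT and 1340 ± 47.4 CPM in KO (adjusted p = 0.44, or 3.7e-07 with the hMSC libraries fitted alone). Of 30 genes of the senescence-associated secretory phenotype 6 rose and 4 fell. IGFBP3, which binds insulin-like growth factors, rose from 114 ± 9.47 to 739 ± 27.2 CPM, and the cytokine IL6 rose from 3.0 ± 0.30 to 16.6 ± 2.71 CPM (adjusted p = 0.015). TNFRSF11B (osteoprotegerin) fell from 82.3 ± 8.22 to 3.33 ± 0.18 CPM, and HGF, hepatocyte growth factor, had 4.96 ± 0.50 CPM in WT and no reads in KO, at least 11.7-fold lower with the limit set at 3 reads per library. The list had a median of 0.28, a mean of -0.17 and no call in camera (adjusted p = 0.7). Of 28 p53 targets GDF15 (30.5 ± 1.60 to 136 ± 12.7 CPM) and PHLDA3 (120 ± 3.11 to 230 ± 4.17 CPM) rose and the death receptor FAS fell (37.5 ± 2.56 to 17.9 ± 2.71 CPM), and the list had no call (adjusted p = 0.38).

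**Figure D1:**
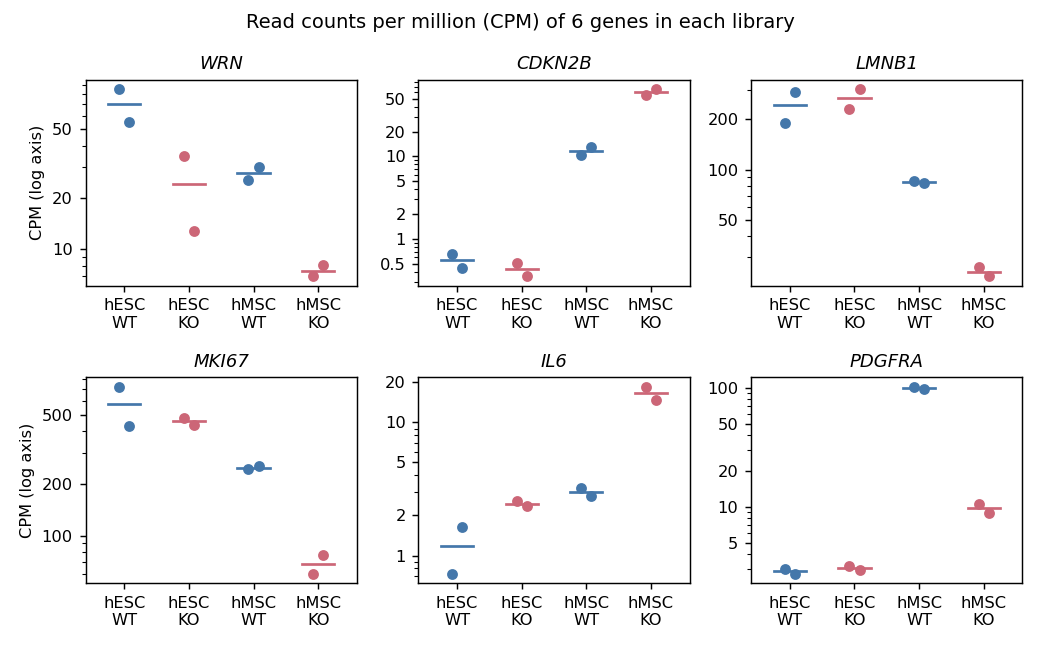
CPM (log axis) of WRN, CDKN2B, LMNB1, MKI67, IL6 and PDGFRA in each RNA-seq library (points, WT blue, KO red), with the group mean as a line (n = 2). In hMSC the KO libraries lie below the WT libraries for WRN, LMNB1, MKI67 and PDGFRA and above them for CDKN2B and IL6.

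Of 22 mesenchymal genes 5 fell and none rose in KO hMSC, while 2 of 36 matrix genes rose and 2 fell. Adjusted over the list alone 1 mesenchymal gene rose and 6 fell. With the hMSC libraries fitted alone 6 mesenchymal genes rose and 10 fell, against 20 and 9 of the matrix genes. In that fit 2038 of all 12096 tested genes rose and 2050 fell. The growth factor receptor PDGFRA fell from 100.2 ± 2.52 to 9.75 ± 1.18 CPM (log2 fold change -3.36, adjusted p = 0.0003) and the surface marker ENG (CD105) from 593 ± 5.16 to 100.2 ± 6.82 CPM. Among the matrix genes COL11A1 (181 ± 2.90 to 1582 ± 44.5 CPM) and the proteoglycan VCAN (73.7 ± 1.66 to 337 ± 31.6 CPM) rose, and BGN, biglycan (874 ± 42.4 to 91.7 ± 2.19 CPM), and POSTN, periostin (78.8 ± 0.12 to 19.3 ± 1.84 CPM), fell. The fibronectin gene FN1 took 1.87 and 1.82% of the reads of the WT hMSC libraries and 4.55 and 4.72% of the KO libraries, without passing the test (adjusted p = 0.23, or 1.8e-20 with the hMSC libraries fitted alone, log2 fold change 1.44). Of 12 smooth muscle genes ACTG2 (36.0 ± 2.31 to 447 ± 37.8 CPM) and CNN1 (46.7 ± 5.90 to 212 ± 8.56 CPM) rose and ACTA2 fell (151 ± 1.20 to 52.2 ± 3.51 CPM). None of these 3 lists passed camera (adjusted p = 0.099, 0.45 and 0.14).

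Markers of other lineages changed in KO hMSC one or a few genes at a time. GATA6, an endoderm and heart regulator, rose from 0.12 ± 0.17 to 22.5 ± 3.29 CPM. TEK, an endothelial receptor, rose from 1.84 ± 0.20 to 15.7 ± 3.17 CPM, the neural regulator ZIC1 from 0.98 ± 0.33 to 11.8 ± 0.43 CPM and DPPA4, of the pluripotency list, from 0.61 ± 0.51 to 12.7 ± 0.50 CPM. POU5F1 had 3.07 ± 0.91 CPM in WT hMSC and 2.53 ± 1.54 CPM in KO hMSC. Among epithelial genes DSP (desmoplakin) rose from 258 ± 0.57 to 1132 ± 46.0 CPM and KRT19 fell from 393 ± 11.8 to 113 ± 7.85 CPM. The homeobox genes HOXB2 and HOXB3 rose from 0.98 ± 0.68 to 27.1 ± 3.32 CPM and from 0.49 ± 0.01 to 13.1 ± 0.20 CPM. PPARG, the regulator of fat cells, rose from 6.61 ± 0.61 to 22.4 ± 3.99 CPM (adjusted p = 0.044). It lies in a run of 46 neighbouring tested genes on chromosome 3 whose median log2 fold change was 0.62 in hMSC and 0.58 in hESC. RPL39L, a ribosomal protein paralog whose reads can be shared with its relatives, fell from 16.5 ± 0.13 to 0.84 ± 0.38 CPM. Each of these lists with 5 or more tested genes had a camera adjusted p of 0.21 or more in hMSC.

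Among the largest rises by the fixed rule were GATA6 and 4 genes without a read in WT hMSC, given against a limit of 3 reads per library. CNTN3 was at least 20.2-fold higher in KO hMSC (7.41 ± 1.53 CPM), NPPB, the natriuretic peptide B gene, at least 16.8-fold (6.16 ± 0.84 CPM) and LHX1 at least 14.7-fold (5.39 ± 1.33 CPM). CGB8, at least 17.9-fold higher (6.56 ± 1.35 CPM), belongs to the chorionic gonadotropin genes, near-identical copies among which reads cannot be assigned with certainty. The largest falls were MAB21L1 (7.84 ± 0.45 CPM in WT, no reads in KO, at least 18.5-fold lower), VIT (32.2 ± 4.39 to 0.14 ± 0.20 CPM), the homeobox gene LHX9 (16.3 ± 2.81 to 0.14 ± 0.20 CPM), the actin-severing protein gene SCIN (135 ± 11.9 to 1.27 ± 0.57 CPM), the integrin gene ITGA8 (30.8 ± 2.91 to 0.36 ± 0.31 CPM) and the mesenchymal regulator HAND2 (33.5 ± 3.20 to 0.50 ± 0.71 CPM).

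Over all 14281 tested genes, 856 passed the threshold in hMSC, 370 higher and 486 lower in KO. Leaving out 1 library changed this count to 259 and 207 without WT hMSC replicates 1 and 2, to 190 and 212 without KO hMSC replicates 1 and 2, and to 1329 without WT hESC replicate 1, and 44 of the 67 named genes lost the call without at least 1 library. DESeq2 called 1322 genes. A fit of the hMSC libraries alone called 4088 of 12096 tested genes, of which 837 were among the 856. Of 32 gene lists tested 4 passed camera in hMSC, and the other 28 had adjusted p from 0.068 to 0.77. With an estimated correlation no list passed in hMSC (smallest adjusted p = 0.12). The fry test, which does not compare a list with other genes, called 9 lists in hMSC and 1 in hESC in one direction.

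In hESC no gene passed the threshold in edgeR's quasi-likelihood test, with 386 genes at an unadjusted p under 0.05 and 36 genes called by DESeq2. Same-numbered hESC libraries deviated together (correlation 0.78), and with the replicate number as a block 483 genes passed. Among pluripotency factors POU5F1 (OCT4) had 1085 ± 576 CPM in WT and 1279 ± 452 CPM in KO, SOX2 234 ± 52.3 and 229 ± 31.8 CPM, NANOG 88.7 ± 53.6 and 138 ± 55.9 CPM, and DNMT3B 1275 ± 327 and 1332 ± 293 CPM. NANOG was higher in KO within each number (50.8 and 98.8 CPM in libraries 1, 126.6 and 177.8 CPM in libraries 2), with an adjusted p of 0.0031 with the block, against 0.15 for POU5F1, 0.79 for DNMT3B and 0.97 for SOX2. PRDM14 had 56.9 ± 5.49 CPM in WT and 86.85 ± 2.60 CPM in KO (adjusted p = 1, or 0.0039 with the block), and NODAL a log2 fold change of 2.01 (SE 0.33, adjusted p = 0.51, or 3.3e-08 with the block). LMNB1 had 242 ± 72.3 CPM in WT and 266 ± 51.6 CPM in KO, CBX5 402 ± 26.7 and 322 ± 98.4 CPM, and MKI67 578 ± 209 and 458 ± 32.6 CPM. CDKN1A had 6.43 ± 0.44 CPM in WT and 16.2 ± 4.82 CPM in KO (log2 fold change 1.33, SE 0.25, adjusted p = 0.51, or 9.1e-06 with the block).

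In hESC 6 of 32 gene lists passed camera although no single gene passed. Of 28 p53 targets 26 had a positive log2 fold change, with a median of 0.25, and 2 rose when adjusted over the list alone (camera adjusted p = 3.3e-07, or adjusted p = 0.12 with an estimated correlation). The 11 tested mesendoderm genes, markers of early differentiation, had a median of 1.09 with 10 positive, and 3 rose when adjusted over the list alone (adjusted p = 1.4e-08, or adjusted p = 0.09 with an estimated correlation). The Nodal antagonist CER1 had log2 fold change 1.76 and T (brachyury) 2.14. The pluripotency list had a median of 0.14 with 15 of 21 positive (adjusted p = 0.00076, or adjusted p = 0.12 with an estimated correlation), led by NODAL (log2 fold change 2.01), LEFTY2 (1.51) and GDF3 (1.5), genes of Nodal signalling. Genes of endoplasmic reticulum stress (median 0.19) and ribosomal protein genes (median 0.16) were shifted up (adjusted p = 0.0019 and 7.5e-05, or adjusted p = 0.58 and 0.78 with an estimated correlation). Genes named ZNF with a number, mostly zinc finger repressors, were shifted down, 318 of 466 being negative with a median of -0.12 (adjusted p = 0.00043, or adjusted p = 0.12 with an estimated correlation).

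The test of whether the KO effect differed between the cell types called 343 genes, 137 with a higher and 206 with a lower log2 fold change in hMSC than in hESC. The G2/M list (median difference -1.93), the DNA replication list (-1.34), the repair list (-0.51), the heterochromatin list (-0.36) and the nuclear envelope list (-0.54) passed camera for this difference (adjusted p = 0.035 or less, or adjusted p = 0.17 or more with an estimated correlation). LMNB1, for example, had a log2 fold change of -1.78 in hMSC and 0.14 in hESC (adjusted p = 0.036 for the difference). Leaving out 1 library changed the count to 22 and 28 without WT hMSC replicates 1 and 2, to 10 and 1 without KO hMSC replicates 1 and 2, to 591 without WT hESC replicate 2 and to 154 without KO hESC replicate 2. DESeq2 called 722.

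**Figure D2:**
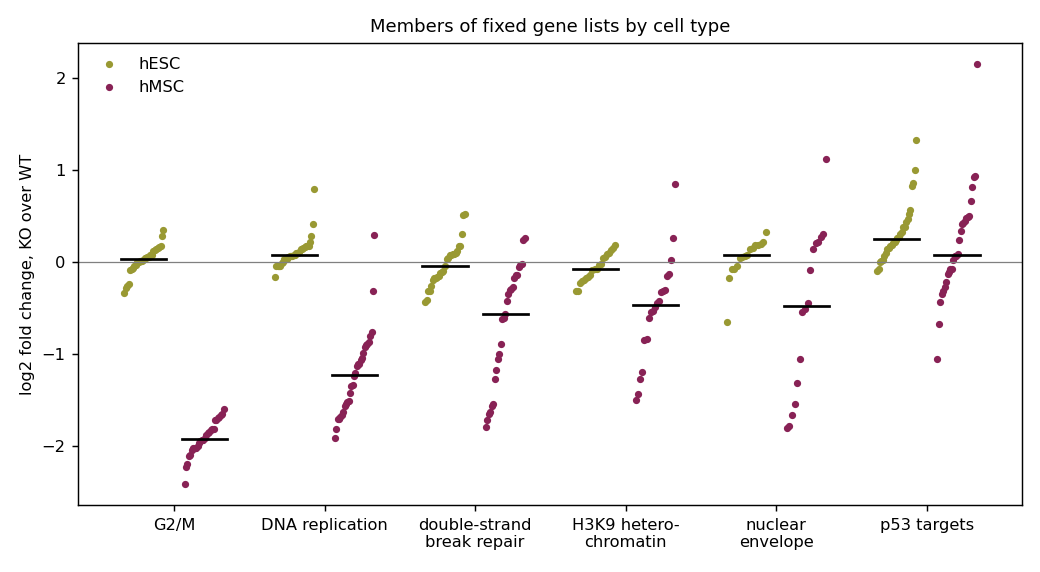
Log2 fold change of KO over WT for each tested member of 6 fixed gene lists in hESC (olive) and hMSC (purple), with the list median as a black line. In hMSC the medians of the G2/M and DNA replication lists were -1.93 and -1.22, against 0.03 and 0.08 in hESC.

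H3K9me3 peaks covered less of the genome in KO hMSC than in WT hMSC with both antibody lots. With lot 1 the 276933 WT peaks covered 162 Mb and the 195922 KO peaks 105 Mb, 64.7% of the WT length. With lot 2 the 140733 WT peaks covered 126.5 Mb and the 29080 KO peaks 26.1 Mb, 20.6% of the WT length. With equal numbers of the highest-scoring peaks, 29080 per library, KO covered 71.4% of the WT length with lot 1 and 58.5% with lot 2. That number is every KO peak of lot 2 but only the highest-scoring part of each other list. The setting therefore does not remove the effect of list length. The mean log2 ratio over the lots was -1.45 (SD 1.17, n = 2), and 2 pairs allow no exact test below 0.05. Of WT peaks 29.6% were overlapped by a KO peak with lot 1 (95% Wilson interval 29.5 to 29.8%) and 7.48% with lot 2 (7.34 to 7.62%), and of KO peaks 43.0 and 35.7% by a WT peak. These shares depend on how many peaks the other list holds. Libraries of the same genotype also shared only part of their peaks. Of WT peaks of lot 1 42.5% were overlapped by a WT peak of lot 2, and 74.1% the other way. For KO peaks these shares were 9.19 and 53.6%. The mean peak score, the authors' own value, was 140 in WT and 107 in KO with lot 1 and 132 and 97.6 with lot 2.

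By position in hg19, the 3 windows of 1 Mb with the largest mean decrease in both lots were chromosome 22 from 49000001 to 50000000, chromosome 7 from 157000001 to 158000000 and chromosome 8 from 143000001 to 144000000. The first was 42.1 and 50.4% covered in WT with lots 1 and 2 and 7.77 and 0.05% in KO. The second went from 36.2 and 38.9% to 6.99 and 0.13%, and the third from 36.4 and 34.3% to 9.46 and 0.46%. Among the windows more covered in KO in both lots, the largest mean increases were on chromosome 21 from 10000001 to 11000000 (8.96 and 7.37% in WT, 14.8 and 7.41% in KO), chromosome 15 from 38000001 to 39000000 (3.36 and 2.57%, 5.44 and 2.98%) and chromosome X from 61000001 to 62000000 (0.51 and 0.27%, 1.70 and 1.39%). Of 2780 windows 2265 (81.5%) were less covered in KO in both lots and 12 more covered in both. By chromosome the log2 ratio was lowest on X (-1.17 and -3.91 with lots 1 and 2) and on chromosome 22 (-1.17 and -3.20). No window passed limma's adjusted threshold (smallest adjusted p = 0.23, 307 windows at an unadjusted p under 0.05), with 1 residual degree of freedom. The same test on simulated data recovered 0% of windows changed by a log2 of 1 or 2, so the count of 0 says little about single windows. Relative to the median window 633 windows passed, 273 higher and 360 lower in KO. With windows of 100 kb 1105 of 23000 passed, 4 higher and 1101 lower, and with peaks of a score of 100 or more 803 passed, all lower.

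**Figure D3:**
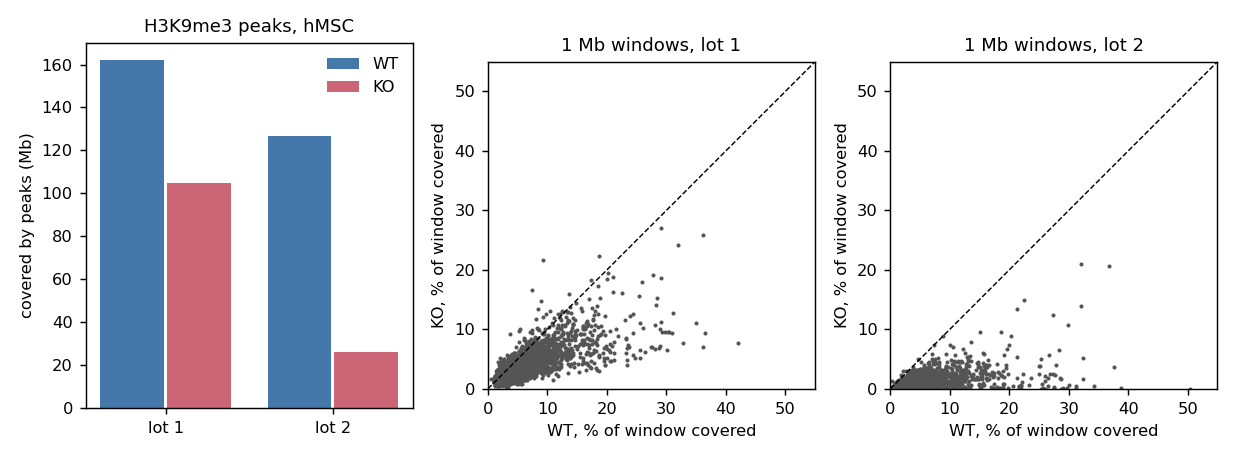
Left, length covered by H3K9me3 peaks (Mb) in WT (blue) and KO (red) hMSC for each antibody lot. Middle and right, percent of each 1 Mb window covered in WT (horizontal) and KO (vertical) for lots 1 and 2, where a point below the dashed line of equal coverage marks a window less covered in KO.

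H3K4me3 peaks were similar in number and position in the 1 WT and 1 KO library. There were 11117 peaks covering 30.8 Mb in WT and 11693 covering 32.2 Mb in KO, and 94.3% of WT peaks (93.8 to 94.7%) and 89.0% of KO peaks (88.4 to 89.5%) were overlapped by a peak of the other genotype. All intervals are 95% Wilson intervals of counting error only, and with 1 library per genotype neither this mark nor H3K27me3 has a replicate check. The highest-scoring KO peaks without overlap were on chromosome 13 from 100634341 to 100640707, chromosome 3 from 147124188 to 147131757 and chromosome 7 from 27134116 to 27144013. The highest-scoring WT peaks without overlap were on chromosome 1 from 235832740 to 235842129 and from 172108377 to 172114887 and on chromosome 19 from 58484892 to 58501432.

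H3K27me3 peaks covered 58.9 Mb in WT (108931 peaks) and 40.1 Mb in KO (75416 peaks), and 20.7% of WT peaks (20.5 to 20.98%) and 29.7% of KO peaks (29.4 to 30.0%) were overlapped by the other genotype. Of 1259 windows of 1 Mb with at least 1% covered in both libraries, 1066 were less covered in KO, with a median log2 ratio of -0.48. The 5 windows of chromosome 3 from 8000001 to 13000000 went the other way, with a median log2 ratio of 1.74. In the window from 10000001 to 11000000 the coverage was 4.19% in WT and 17.1% in KO. Lot 1 H3K9me3 coverage of the 5 windows, as percent plus 1, had a median log2 ratio of 1.06, against -0.37 over all tested windows, while lot 2 coverage was lower in KO in all 5, with a median of -0.49 against -1.25. RRBS reads in them were 1.39 times as many in KO relative to the median window. The highest-scoring KO peaks without overlap were on chromosome 4 from 174452064 to 174455545, chromosome 3 from 10579090 to 10581818, inside those windows, and chromosome 2 from 236066202 to 236068770. In WT they were on chromosome 13 from 100623864 to 100626630, chromosome 3 from 186364901 to 186367803 and chromosome 8 from 130754987 to 130757504.

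**Figure D4:**
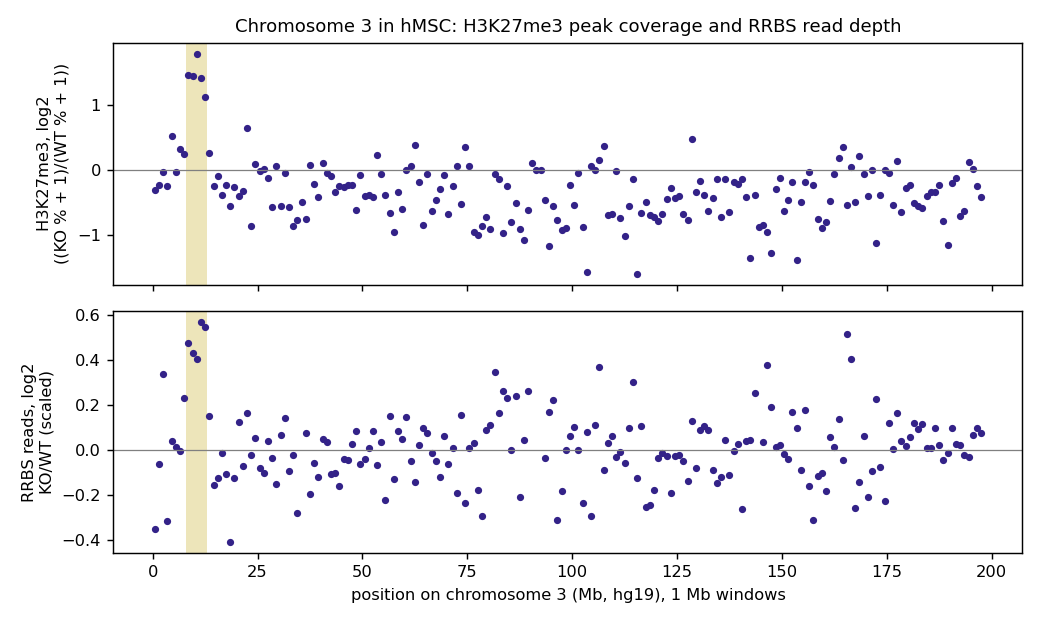
Chromosome 3 in 1 Mb windows by hg19 position (Mb). Top, log2 of KO over WT for the percent covered by H3K27me3 peaks plus 1; bottom, log2 of KO over WT for RRBS reads scaled by the median window of the genome. The shaded windows are the 5 from 8000001 to 13000000, where the RRBS values lie between 0.41 and 0.57.

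At the sites tested, DNA methylation of hMSC was high and on average similar in the 1 WT and 1 KO library. Of 2870724 CpG sites listed in both, 270464 had at least 10 reads in both (median 16.0 and 15.0 reads). Over these the mean level was 83.0% in WT and 84.1% in KO. Fisher's exact test with Benjamini-Hochberg adjustment called 7625 sites with a difference of at least 20 percentage points, 4547 higher and 3078 lower in KO, which compares these libraries and not the genotypes. On simulated data with 500 of 50000 sites changed by 40 points the test recovered 9.0% of them. That result depends on the share of sites changed as well as on depth, so it does not give the power of the real test. Many differences of that size may have been missed. Sites in WT H3K4me3 peaks had 28.3% in WT and 28.0% in KO, sites in WT H3K27me3 peaks 62.6 and 63.9%, and sites in WT H3K9me3 peaks of lot 1 81.0 and 82.1%. The tiles of 1 kb with the largest increase were on chromosome 20 from 57465001 to 57466000 (0.0 to 76.9% over 27 sites), chromosome 1 from 110950001 to 110951000 (21.3 to 95.4% over 9 sites) and chromosome 1 from 17020001 to 17021000 (20 to 94.0% over 10 sites). The largest decreases were on chromosome 5 from 126565001 to 126566000 (81.0 to 5.6% over 12 sites), chromosome X from 153600001 to 153601000 (81.7 to 9.1% over 6 sites) and chromosome 17 from 58216001 to 58217000 (79.9 to 8.2% over 11 sites). Of 19261 tiles with 5 or more such sites 506 were higher and 328 lower in KO by at least 20 points.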

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

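The results here were listed because the KO effect in hMSC differed from that in hESC by the planned test of the difference itself, and no further test was run on them. That test called 343 genes. Values are the log2 fold change in hMSC minus that in hESC. No explanation of these differences was tested, and the hESC libraries of each pair differed far more than the hMSC libraries (mean chi-square per gene 105 and 90.8 against 2.42 and 4.34).

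Among cell cycle, replication and repair genes the difference was -2.55 for KIF20A, -2.40 for AURKB, -1.99 for MCM5 and -1.55 for BRCA1. The median over the G2/M list was -1.93, over the DNA replication list -1.34 and over the repair list -0.51. With an estimated correlation none of the 5 list differences given here passed (adjusted p = 0.17 or more). Among genes of the nuclear envelope and chromatin it was -1.92 for LMNB1, -1.50 for LBR, -1.70 for TMPO and -1.94 for EZH2, with list medians of -0.54 for the nuclear envelope and -0.36 for the heterochromatin factors. The inhibitor gene CDKN2B had a difference of 2.74.

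Among secreted, matrix and mesenchymal genes the difference was 2.77 for IGFBP3, -5.81 for TNFRSF11B, 2.91 for COL11A1, -3.13 for BGN, -2.38 for POSTN and -3.46 for PDGFRA. For the smooth muscle genes ACTG2 and ACTA2 it was 3.56 and -1.69. Among markers of other lineages it was 4.25 for DPPA4, 2.80 for TEK, 4.51 for ZIC1, 6.32 for GATA6 and -1.76 for KRT19. It was -7.31 for SCIN and -3.72 for RPL39L, a ribosomal protein paralog with relatives that can share reads. For 4 genes a group had no reads, so only the adjusted p of the difference is given: 0.023 for HOXB3, 0.048 for CNTN3, 0.044 for NPPB and 0.029 for NIPAL4. Some of the other differences also rest on few reads. GATA6 had 2 and 0 reads in the WT hMSC libraries (SE of the difference 0.87) and ZIC1 6 and 10 (SE 0.82). TNFRSF11B had 4 and 16 reads in the WT hESC libraries (SE 0.56).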

How the results depend on the processing

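The fits of the compared groups with the replicate block were chosen after the data were seen. So were the counts of list members with the hMSC libraries fitted alone. The other alternatives were planned. With the replicate number as a block 3605 genes passed in hMSC, 483 in hESC and 2429 for the difference between cell types. With the compared groups alone 4088 passed in hMSC, and with the block as well 4221 in hMSC and 733 in hESC. DESeq2 called 1322, 36 and 722. With each library left out the counts were 190 to 1329 in hMSC, 0 to 1 in hESC and 1 to 591 for the difference, with the lone library assumed to vary like the other groups. The camera calls went from 4 lists in hMSC and 6 in hESC to 0 in both with an estimated correlation. Same-numbered hESC libraries deviated together (correlation 0.78) and hMSC libraries did not (0), and 2 pairs cannot establish pairing. With the block, 483 hESC genes where none passed without it, a difference between the hESC libraries numbered 1 and 2 is a candidate explanation for the count of 0. The WT comparison of cell types stayed within 1.5 times its count under every alternative run.

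Of H3K9me3 windows 1 passed without a replicate block, 633 relative to the median window (273 higher and 360 lower in KO), 1105 with 100 kb windows (4 higher and 1101 lower), 803 with a score of at least 100, all lower, and 2 with a pseudocount of 0.1, both lower. Leaving out a library left no residual degree of freedom, so those fits were not run. The H3K9me3 length ratio was negative under every alternative run, from -2.28 to -0.63 as a mean log2 ratio, the upper end with equal numbers of peaks and with lot 1 alone. The setting with equal numbers still took a smaller share of the longer WT lists than of the KO lists. The H3K4me3 shares of WT and KO peaks were 95.8 and 86.3% with a score of at least 100, 93.8 and 88.2% with an overlap of at least 50%, and 92.8 and 91.9% with equal numbers of peaks. For H3K27me3 they were 12.1 and 18.6% with an overlap of at least 50%, and 23.7 and 24.1% with equal numbers, and a score of 100 removed no peak. RRBS calls were 2375 with at least 20 reads, where 45846 sites were tested, and 15802 with strands summed. Causes of the other changes were not tested. Of 93 named results 31 kept their side of the threshold and direction in every alternative run, and none reversed. The planned comparison of marks with RNA was not run, since no hg19 annotation was used here.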

Other observations

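The tests of chromosome ends and of the X-linked neighbours, and the limits used for the zinc finger genes, were chosen after the result was seen. Genes outside the naming rule are named here after their values were seen. Of the genes with the smallest p in hMSC, some outside the fixed lists are given with what they encode, and no enrichment among them was tested. The chemokine gene CXCL12, which marks marrow stromal cells, fell from 1890 to 90.5 CPM (log2 fold change -4.39, SE 0.23, adjusted p = 0.00019), DIO2, which activates thyroid hormone, from 233 to 11.9 CPM (-4.29, SE 0.18) and the hypoxia regulator EPAS1 from 263 to 32.9 CPM (-3.00, SE 0.21). INHBA, the activin A subunit, rose from 50.8 to 419 CPM (3.04, SE 0.18), its antagonist FSTL3 from 56.7 to 282 CPM (2.32, SE 0.17), HBEGF from 60.4 to 262 CPM (2.12, SE 0.16) and the potassium channel gene KCNG1 from 27.9 to 277 CPM (3.31, SE 0.18). ANKRD1, a target of YAP signalling, rose from 236 to 1260 CPM and the cyclin gene CCND2 from 6.31 to 58.3 CPM, while HMGB2, a chromatin protein of dividing cells, fell from 154 to 27.2 CPM.

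The zinc finger genes ZNF229 and ZNF502 had reads in both WT hESC libraries and almost none in the KO hESC libraries. ZNF229 had 3.63 and 6.77 CPM in WT hESC and no reads in KO hESC, and 0.742 and 0.971 CPM in WT hMSC against 0.0 and 0.288 CPM in KO hMSC. ZNF502 had 4.36 and 4.32 CPM in WT hESC and 0.0 and 0.04 CPM in KO hESC, and 1.73 and 3.40 CPM in WT hMSC against no reads in KO hMSC. Neither passed in hESC (adjusted p = 0.36), while ZNF502 passed in hMSC (adjusted p = 0.023). They were the only genes with at least 3 CPM in both WT and under 0.2 CPM in both KO hESC libraries, and no gene had the opposite pattern.

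On chromosome 3, the 5 windows from 8 to 13 Mb (hg19) carried more H3K27me3 and lot 1 H3K9me3 in KO hMSC, where most windows carried less, while lot 2 H3K9me3 was lower in KO in all 5 (median log2 ratio -0.49, against -1.25 over all windows). RRBS depth over them had a median log2 ratio of 0.48 (0.41 to 0.57 in single windows, upper end of the central 95% of all windows 0.29). The 46 neighbouring tested genes from OXTR to IQSEC1 had a median log2 fold change of 0.62 in hMSC, where the central 95% of runs of that length end at 0.2. The same genes had a median of 0.58 in hESC, where the central 95% of runs end at 0.08. The highest of 13204 runs of that length had a median of 0.62 in hMSC and 0.59 in hESC. Of the 46 genes 42 were above 0 in hESC and 37 in hMSC. Those that passed the threshold as higher in KO numbered 0 in hESC and 2 in hMSC. These values are consistent with additional DNA copies of the segment in KO cells of both types, a candidate explanation for its marks and for part of the rise of PPARG. With 1 RRBS library per genotype, a difference in chromatin state stays open. Additional copies could also be a trait of the clone used rather than an effect of losing WRN.

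H3K9me3 coverage was lower in KO hMSC by a larger share in 51 windows with at least 20% covered in both WT libraries. All 51 were less covered in KO in both lots, as were 81.5% of the 2780 tested windows. They were chosen on the WT values that KO coverage is divided by, which favours a larger decrease in advance. KO coverage of the 51 windows was 38.4% of WT with lot 1 and 13.1% with lot 2, against 67.1 and 21.6% in the 2729 other windows. Loss of the DNA is argued against by their RRBS depth, with a median log2 ratio of -0.03 and a lowest value of -0.17. Of the 51 windows 40 are among the 219 tested windows within 5 windows of the first or last window with peaks on a chromosome. There KO coverage as a share of WT was lower than elsewhere (log2 of the 2 shares -0.78 with lot 1 and -1.03 with lot 2). Without the 51 windows themselves that share was 45.0 and 12.4% at the ends against 70.5 and 23.2% elsewhere (one-sided permutation p = 0.00073 and 0.0018 over 2728 shifts along the genome). These p-values measure the spread along the genome within the libraries of a lot, not between libraries or genotypes. The end windows kept can lie next to those left out, so they are not an independent check. Position at a chromosome end is a candidate explanation for where the decrease was larger. Lower enrichment of the KO libraries as the whole cause cannot be told apart from loss of the mark: the highest-scoring WT peaks were overlapped by KO peaks less often inside these windows, by -8.0 percentage points with lot 1 and -5.3 with lot 2, which lies short of the 10 points set beforehand.

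On the X chromosome 9 neighbouring tested genes from TIMM17B to CCDC120 had a median log2 fold change of 0.95 in hESC and 0.87 in hMSC, where the central 95% of runs of 9 genes end at 0.2 and 0.5, and 8 of the 9 were above 0.5 in both cell types. The remaining gene, KCND1, had 0.35 and -1.34. In hMSC SLC35A2 (1.09, adjusted p = 0.012), OTUD5 (0.97, adjusted p = 0.027) and PIM2 (1.00, adjusted p = 0.048) passed the threshold. By its hESC median the run from TIMM17B to CCDC120 ranked with the highest of 14055 runs. Its place above the hESC limit is therefore not a test. No explanation was tested.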
